A study of Drosophila melanogaster with 24 samples.

How the data were processed

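Kc167 cells were mock treated or transfected with 12 µg of double-stranded RNA against Isha and collected after 5 days, per the labels' protocols. Chromatin was precipitated with antisera against Isha, Su(Hw), CP190 and Mod(mdg4)67.2, and inputs were sequenced beside them. The 24 libraries make 12 groups of 2 replicates: 4 antibodies and 2 kinds of input in each treatment. Per the labels, the replicates of Isha were made with different antisera. Nothing says whether replicates came from separate cultures.

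The submitters' processing notes name Bowtie2 2.4.1, SAMtools 1.9, Picard 2.22.2 and the genome build dm6. The peak caller, its threshold and the way replicates were joined are not given in the sources used here. The deposited files are 8 lists of peaks with chromosome, start and end only, 1 list per antibody and treatment, named as overlaps, which was read as peaks joined over both replicates. Their group was taken from the names of the lists, and "SwHw" in one name was read as Su(Hw), the only antibody otherwise without a knockdown list. The lists hold no score, fold, read count or replicate column, so depth is unknown, no peak height could be compared, and a lost peak may be a weaker one that fell below the authors' threshold. If the name means peaks found in both replicates, a lost peak may also be a peak missed in a single knockdown replicate. No column of another sample was present.

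Peaks were used as deposited, on the main arms 2L, 2R, 3L, 3R, 4 and X, which left out 1 to 5 peaks per list, all on Y. Coordinates are given counted from 1. Peaks were called shared at an overlap of at least 1 bp. Shares have Wilson and differences of shares Newcombe intervals at 95%, which cover counting error only. Peaks within a list are not replicates, and neighbouring peaks are not independent. The share of mock peaks kept after knockdown was set beside 1000 random placements on the same arm with widths kept. Sharing between the mock lists was tested against 1000 such placements, one-sided, with Benjamini-Hochberg adjustment over 6 protein pairs, and again with placements that keep the distance of each peak to the nearest gene end. Kept shares with and without Isha were set beside 10000 random sets of peaks matched on width in 10 bins, as a description of these lists.

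Genes came from a RefSeq table of the same assembly (Release 6 plus ISO1 MT), with 13922 protein-coding genes on the main arms. The design fixed before the data were examined had assumed transcription start sites, but the table gives no strand, so both ends of a gene were used: a peak counts as near a gene end when its midpoint is within 500 bp. The 8 gene groups, fixed before the data were examined, were tested by counting genes with a peak within 1000 bp against 10000 random gene sets matched on gene length, two-sided, with Benjamini-Hochberg adjustment over 64 tests. All symbols matched the table; nos was taken as nanos, and Eip71CD is listed as MsrA. Genes were named by a rule fixed before the data were examined: for each group up to 6 examples in the order of its list, first those with a peak, and for each class of Isha, lost or gained peaks the 5 or 10 widest, since the lists hold no score. Where a name falls outside that rule the text says so; the neighbourhoods of the Isha, Cp190 and su(Hw) genes are those of genes in the first group.

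Computation used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and figures were drawn with matplotlib 3.10.9. The steps were tested on simulated data. Lists made to share 28.7% of the 4735 Isha peaks gave 31.4%, chance overlap included. When the kept share of 4900 simulated Su(Hw) peaks only followed width, 2.5% of 200 runs fell below the 2.5 percentile of width-matched sets, and with a drop of 15 points all did. In these runs the kept share rose evenly with the rank of width, so loss concentrated among the narrowest peaks was not simulated. Random sets of 24 genes passed the gene group test for the mock Isha list in 2.5% of 200 runs, and sets with a peak at about 90% of their genes in all.

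Alternatives were 50% reciprocal overlap, midpoints within 250 bp, merging of peaks within 500 bp, all sequences, base pairs covered in place of peak numbers, gene-end windows of 250 and 1000 bp, placements matched to gene ends, and subsets by width and position. Motif shares were not computed because no genome sequence was used here, and a stricter peak threshold was not run because the lists hold no score.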

Results

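The series profiled Isha and 3 insulator proteins by chromatin immunoprecipitation and sequencing (ChIP-seq) in Kc167 cells, a female Drosophila line derived from embryos. Insulator proteins bind DNA elements that keep enhancers and promoters, or chromatin domains, apart. Su(Hw) is the zinc finger protein that recognises the gypsy class of insulator. CP190 and the 67.2 isoform of Mod(mdg4) are partners found in the same complexes. Isha, the product of CG4266, is described in the title of the series as a protein that binds su(Hw) mRNA. Cells were treated with double-stranded RNA against Isha, or mock treated, and the stated questions were where Isha lies relative to the other 3 proteins and whether their binding depends on it. Of the 24 libraries, 16 were immunoprecipitates and 8 were inputs, with 2 replicates in each of 12 groups. The deposited data used here were 8 peak lists, 1 per antibody and treatment, with positions in dm6 and no score. On the main arms (2L, 2R, 3L, 3R, 4 and X) the mock lists held 4735 Isha, 4900 Su(Hw), 8193 CP190 and 1305 Mod(mdg4) peaks, and the knockdown lists held 932, 4711, 8880 and 1091. With 1 list for both replicates, no difference between mock and knockdown has a replicate check, none is given a p-value, and the intervals below are 95% intervals that cover counting error over peaks only.

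The targeted protein was looked at first. The Isha list shrank from 4735 peaks in mock cells to 932 after knockdown, a ratio of 0.197. Of the mock peaks, 893 (18.9%, Wilson interval 17.8 to 20.0%) overlapped a knockdown peak, against 2.59% for randomly placed peaks of the same widths. Wide Isha peaks remained more often. With mock peaks parted by width into 4 equal sets, 3.55% of the narrowest were kept (2.63 to 4.76%), and the next sets followed with 10.8%, 19.8% and 41.3% (38.5 to 44.1%). Mock peaks with Mod(mdg4) were kept more often than peaks of like width, at 37.0% of 81 peaks (27.3 to 47.9%) against a mean of 15.1% in width-matched random sets. Those with none of the 3 insulator proteins were kept in 10.3% of 1534 cases (8.88 to 11.9%), against 12.5% in width-matched sets. On chromosome 4, none of 30 Isha peaks was kept, with a Wilson upper bound of 11.4%, and on the other arms the kept share ran from 13.3% on 3R to 24% on 3L. Only 41 knockdown Isha peaks had no mock counterpart. Under stricter definitions of a shared peak the kept share was lower, at 14.1% for 50% reciprocal overlap and 9.48% for midpoints within 250 bp.

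The 5 widest Isha peaks found in both treatments lay at or near CG15456 (X, 20422298 to 20431640), Vsp37A (X, 618984 to 627498), Noc2 (2L, 21161999 to 21169949), Gbeta13F, a G protein subunit gene (X, 15856099 to 15863936), and CG14478 (2R, 17455977 to 17463645). Each of the 5 also held a CP190 peak in both treatments, and the peak near Vsp37A a Su(Hw) peak. The Isha gene itself (2R, 21161713 to 21168659) kept its peak: the mock peak spanned 21167198 to 21171973 and the knockdown peak 21166940 to 21172241. Cp190 held Isha peaks at 15267387 to 15269805 and at 15272877 to 15276545 on 3R in mock cells, and a knockdown peak at 15273697 to 15276456.

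**Figure D1:**
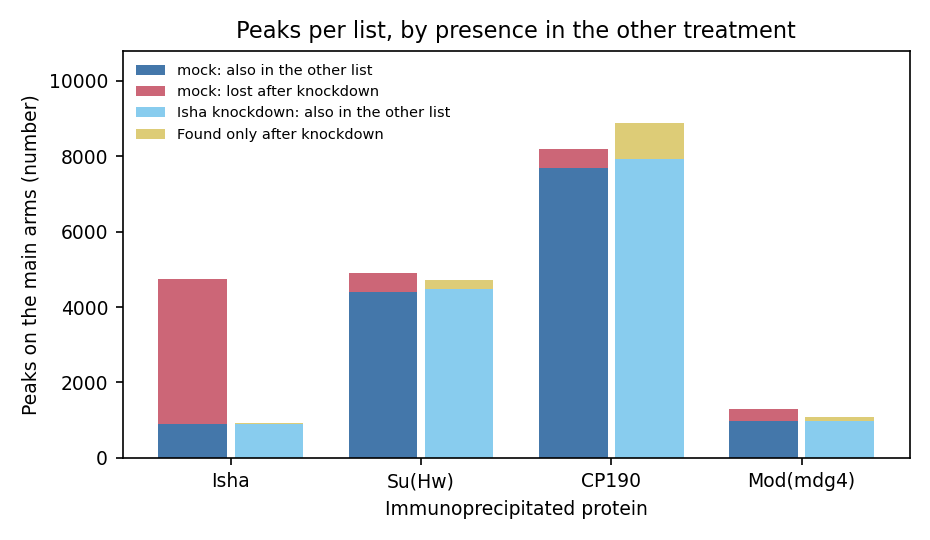
Number of peaks on the main arms (y axis) for each immunoprecipitated protein (x axis), with the mock list on the left and the Isha knockdown list on the right of each pair. Colours part peaks that overlap a peak of the other treatment from those that do not: 3842 of the 4735 mock Isha peaks had no knockdown counterpart, against 507 of 8193 for CP190.

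In mock cells Isha lay at genes. The midpoints of 57.2% of Isha peaks (55.8 to 58.6%) were within 500 bp of an end of a protein-coding gene, against 15.1% of random placements. Midpoints inside a gene made up 85.4% for Isha, against 67.3% of random placements (65.1 to 68.5% over 100 of them), while Su(Hw) with 59.9%, Mod(mdg4) with 51.9% and CP190 with 50.9% lay below the lowest of their placements. CP190 had 50.3% near gene ends (49.2 to 51.4%), while Mod(mdg4) with 25.4% (23.2 to 27.9%) and Su(Hw) with 18.2% (17.2 to 19.3%) were closer to placement, which gave 15.1%. In all, 6922 of 13922 protein-coding genes (49.7%) had a mock Isha peak within 1000 bp, 8488 had a CP190 peak, 3145 a Su(Hw) peak and 1146 a Mod(mdg4) peak. The gene table gave no strand, so promoters and transcript ends were not told apart, and the shares depend on the window: Isha had 32.2% within 250 bp and 73.0% within 1000 bp.

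Isha peaks overlapped CP190 peaks far more often than Su(Hw) or Mod(mdg4) peaks. Of the 4735 mock Isha peaks, 3171 (67.0%, 65.6 to 68.3%) overlapped a CP190 peak by at least 1 bp, 340 (7.18%, 6.48 to 7.95%) a Su(Hw) peak and 81 (1.71%, 1.38 to 2.12%) a Mod(mdg4) peak. CP190 alone was found at 2855 (60.3%), all 3 proteins at 75 (1.58%, 1.27 to 1.98%) and none of them at 1534 (32.4%). The insulator proteins by contrast shared sites with each other: 98.0% of Mod(mdg4) peaks overlapped Su(Hw), 98.1% overlapped CP190, and 77.3% of Su(Hw) peaks overlapped CP190. CP190 peaks with Su(Hw) seldom carried Isha. It was at 8.40% of the 3856 CP190 peaks with Su(Hw) (7.57 to 9.32%) and at 66.2% of the 4337 without it (64.7 to 67.5%).

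Random placement of the Isha peaks on the same arm gave 19.2% with CP190 on average, so the observed share was 3.48-fold higher (one-sided permutation test over 1000 placements, p = 0.001, the smallest they can give, adjusted p = 0.0015 over 6 protein pairs). Placements that kept each peak's distance to a gene end gave 37.6% with CP190 and at most 39.9%, for a fold of 1.78 (permutation p = 0.001). For Su(Hw) the observed share was below placement, at 0.600 times its mean of 12.0% and 0.677 times the 10.6% of placements matched to gene ends. The planned one-sided permutation test for a higher share gave p = 1 for Su(Hw) and for Mod(mdg4). A test in the lower direction, added after the values were seen, gave a permutation p = 0.001 for both. The direction for Mod(mdg4) turned with the definition of overlap: its fold over placement was 0.664 as reported, 1.56 with 50% reciprocal overlap and 1.22 with midpoints within 250 bp. The test for a higher share then passed for reciprocal overlap (permutation p = 0.01) and did not for midpoints (permutation p = 0.1768). Under those definitions the share with CP190 was 27.7% and 18.4%, that with Su(Hw) 1.75% and 1.41%, and that with all 3 proteins 0.338% and 0.380%, while the fold for CP190 over placement was 5.17 and 6.02.

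**Figure D2:**
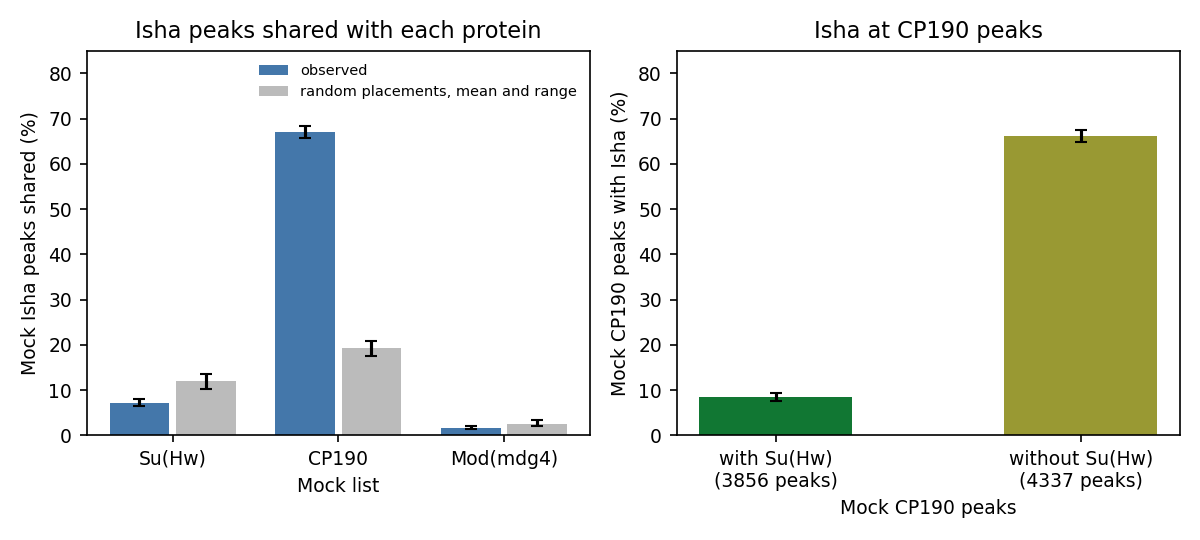
Left, percent of mock Isha peaks (y axis) that overlap a mock peak of each insulator protein (x axis), observed with Wilson 95% intervals and in 1000 random placements with their lowest and highest values; CP190 stands at 67.0% against 19.2%. Right, percent of mock CP190 peaks that carry Isha, with Wilson 95% intervals, for CP190 peaks with Su(Hw) (8.40%) and without it (66.2%).

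Among the 10 widest Isha peaks that overlapped all 3 proteins were sites in cbt, a zinc finger transcription factor gene (2L, 476853 to 480505), ush, a cofactor of GATA factors (2L, 489920 to 492711), the phosphatase gene Ptp61F (3L, 1349618 to 1352309), RpLP0, a ribosomal protein gene (3L, 22074729 to 22078284), and the ATP synthase gene blw (2R, 22798414 to 22801061). The widest lay inside Snap25, a synaptic fusion gene (3L, 24168842 to 24176111). There the mock and knockdown lists of Su(Hw), CP190 and Mod(mdg4) all held a pair of peaks with nearly the same edges, such as 24168959 to 24173722 for mock Su(Hw), 24168953 to 24173728 for mock CP190 and 24168968 to 24173712 for mock Mod(mdg4). The next widest, inside Myo81F (3R, 2084918 to 2089546), was also present in all 8 lists. So were the sites named above in cbt, ush, Ptp61F and RpLP0. The 5 widest Isha peaks with none of the 3 proteins lay in ush (2L, 529223 to 536873), in the signalling inhibitor gene sty (3L, 3410346 to 3417225), in hang (X, 16423647 to 16430233), in the translation factor gene eIF5B (3L, 3426103 to 3432003) and at CG32221 (3L, 19832244 to 19838051). Of these, the sites in ush and sty were kept after knockdown.

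Isha was common at genes for ribosomal proteins and for insulator and architectural proteins, and rare at Hox and segmentation genes, which pattern the body axis. A mock Isha peak lay within 1000 bp of 80 of 88 ribosomal protein genes, against 40.5 in random sets of genes of like length, and of 25 of 27 insulator and architectural protein genes, against 14.8 (two-sided permutation tests over 10000 sets, adjusted p = 0.0032 for each). The insulator and architectural protein genes with a peak included su(Hw), Cp190, mod(mdg4), Isha, shep, an RNA-binding cofactor of insulators, and CTCF, and those without were insv and Elba1, named after their values were seen. The ribosomal protein genes included RpL36, RpL22, RpL35, RpL7A, RpL17 and RpS6, each of which also had a CP190 peak. Of 16 Hox and segmentation genes only lab had an Isha peak, against 8.26 in random sets (permutation test, adjusted p = 0.0077), and pb, zen, bcd, Dfd and Scr had none. With peaks counted only within 500 bp of a gene end, these 3 calls stayed on the same side, with 78, 23 and 0 genes.

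Su(Hw) instead lay at more neuronal genes than random sets when peaks along the whole gene were counted. It had a mock peak at 20 of 24 of them, against 13.5 in random sets (permutation test, adjusted p = 0.0329), among them the synaptic vesicle genes nSyb and Syt1, the active zone gene brp, fne, the sodium channel gene para and the GABA receptor gene Rdl. The genes without one were elav, Syx1A, ple and futsch, named after their values were seen. Isha was at 6 of the 24, against 12.2 (permutation test, adjusted p = 0.1248). CP190 lay at 82 of 88 ribosomal protein genes, against 46.9 (permutation test, adjusted p = 0.0032). Gene length was matched by decile only, so the longest neuronal genes may be matched only in part. Within 500 bp of gene ends the neuronal count for Su(Hw) was 12 against 6.56, which no longer passed (permutation test, adjusted p = 0.1779), and the Isha count was 3 against 9.68, which did (permutation test, adjusted p = 0.0439).

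The remaining groups did not pass in any mock list. Isha was at 7 of 14 germline genes, 10 of 19 heat shock genes, 9 of 15 ecdysone genes and 6 of 15 blood cell genes, against 8.12, 10.4, 7.33 and 7.91 in random sets. Su(Hw) was at 5, 1, 9 and 5 genes of these groups, CP190 at 12, 9, 13 and 8, and Mod(mdg4) at 1, 0, 7 and 2. The 7 ecdysone genes with Mod(mdg4) included EcR, the hormone receptor gene, and the early response genes Eip74EF, Eip75B and Eip78C, against 3.6 in random sets (permutation test, adjusted p = 0.36). The lowest adjusted permutation p of these 16 tests was that value. The groups were tested over 64 combinations of list and group.

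**Figure D3:**
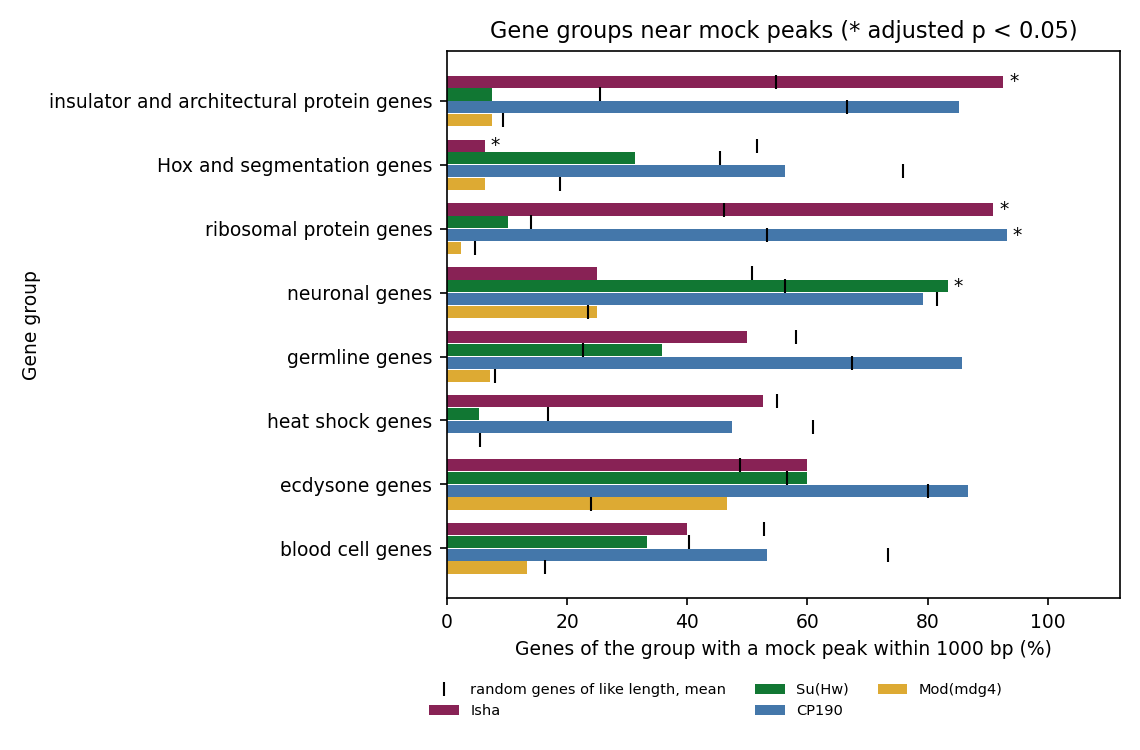
Percent of the genes of each group (y axis) with a mock peak of each protein within 1000 bp (x axis); black ticks mark the mean of 10000 random gene sets of like length, and asterisks mark an adjusted permutation p below 0.05. Isha reached 90.9% of ribosomal protein genes and 6.25% of Hox and segmentation genes, and Su(Hw) reached 83.3% of neuronal genes.

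After Isha knockdown most sites of the insulator proteins were still called. Of the mock peaks, 93.8% were kept for CP190 (93.3 to 94.3%), 89.9% for Su(Hw) (89.0 to 90.7%) and 74.0% for Mod(mdg4) (71.6 to 76.3%), against 17.5%, 10.3% and 1.42% for random placement and against 18.9% for Isha. The number of peaks moved by ratios of 0.961 for Su(Hw), 1.08 for CP190 and 0.836 for Mod(mdg4). CP190 had more peaks but covered less sequence, 0.868 times the mock base pairs. Peaks found in both treatments were narrower after knockdown, with median width ratios of 0.887 for Su(Hw), 0.856 for CP190, 0.889 for Mod(mdg4) and 0.814 for Isha itself. Lost peaks were narrow: their median mock width was 787 bp for Su(Hw), 894 bp for CP190 and 701 bp for Mod(mdg4), against 1579, 1448 and 914 bp for kept ones. Peaks found only after knockdown numbered 222 for Su(Hw), 964 for CP190 and 119 for Mod(mdg4).

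Loss at Isha sites differed in sign between Su(Hw) and CP190. Su(Hw) peaks with a mock Isha peak were kept less often than those without, 237 of 319 (74.3%, 69.2 to 78.8%) against 90.9% of 4581, a difference of -16.6 points (Newcombe interval -21.8 to -12.1). CP190 peaks with Isha were kept more often, 97.3% of 3193 against 91.6% of 5000, a difference of 5.73 points (4.76 to 6.68). For Mod(mdg4) the shares were 82.7% of 81 and 73.4% of 1224, a difference of 9.27 points whose interval (-0.69 to 16.4) includes 0. Random sets of Su(Hw) peaks matched on width were kept at 81.2% on average (central 95% of sets 77.7 to 84.6%), so the observed 74.3% lay below all 10000 sets. For CP190 the width-matched mean was 94.9% and the observed share lay above all sets, and for Mod(mdg4) it stood at percentile 95.3. The size of the Su(Hw) difference depended on the peaks compared: -23.4 points near gene ends, -5.67 away from them, -3.90 among peaks of middle width, and -7.36 with 50% reciprocal overlap. With midpoints within 250 bp it was -5.63 points over 67 peaks with Isha, and the interval (-17.1 to 3.05) included 0. For CP190 it was 1.22 points among peaks of middle width and 2.62 near gene ends.

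The widest Su(Hw) peaks with mock Isha that had no knockdown counterpart lay at an end of Galphaq, a G protein gene (2R, 12611966 to 12613578), between genes near Tif-IA (2L, 22280688 to 22282209), next to CG33557 (X, 10009468 to 10010695), in BNIP3 (3L, 20516136 to 20517295) and next to CG9902 (X, 16547250 to 16548408). All 5 kept a CP190 peak. The site near Tif-IA, 23189 bp from that gene, also kept its Isha and Mod(mdg4) peaks, while the others had no knockdown Isha peak. CP190 peaks with mock Isha that were lost included sites at CG40228 (3L, 27082436 to 27085295), mask (3R, 24233166 to 24235480), CG12567 (2L, 23173157 to 23175262) and PlexA, an axon guidance receptor gene (4, 1026355 to 1028278). The widest Mod(mdg4) peaks found only after knockdown lay at CG17778 (X, 493880 to 495170) and at srp, a GATA factor gene of blood cells (3R, 16003774 to 16004949). The next widest lay at Nepl4, slo and CG30379. At each of these sites Su(Hw) and CP190 peaks were present in both treatments. Those at Nepl4, slo and CG30379 had an Isha peak in mock cells only, and those at CG17778 and srp had none. Su(Hw) peaks with Mod(mdg4) were kept in 99.5% of 1212 cases (98.9 to 99.8%). Without Mod(mdg4) the share was 86.7%. Of the Su(Hw) peaks with Isha, the 79 that also had Mod(mdg4) were kept in 77 cases (Wilson interval 91.2 to 99.3%) and the 240 without it in 66.7% (60.5 to 72.3%). Peaks with Mod(mdg4) were also wider, with a median of 1859 bp against 1330 bp, and 1665 bp against 999.5 bp among those with Isha. These splits were not matched on width, so an effect of Mod(mdg4) is not read from them.

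**Figure D4:**
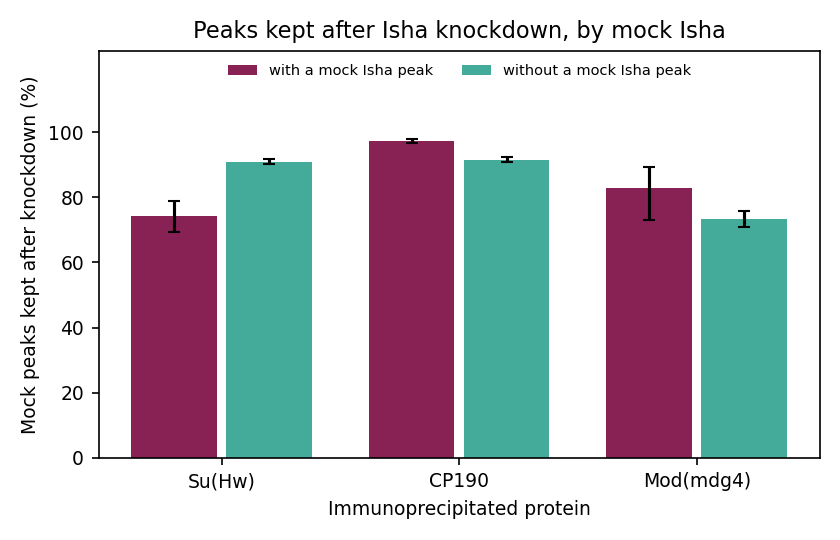
Percent of mock peaks that overlap a knockdown peak (y axis) for each insulator protein (x axis), for peaks with and without a mock Isha peak, with Wilson 95% intervals. Su(Hw) peaks with Isha stand at 74.3% against 90.9% without, while CP190 peaks stand at 97.3% against 91.6%.

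Peaks called only after knockdown were also unevenly placed relative to mock Isha. Of the 222 Su(Hw) peaks found only after knockdown, 21.6% (16.7 to 27.5%) lay at a mock Isha peak, against 5.10% of those found in both treatments and 11.3% in width-matched sets. For Mod(mdg4) the shares were 22.7% (16.1 to 31.0%), 6.79% and 7.46%. For CP190 the share of 32.8% (29.9 to 35.8%) was below the 39.5% of shared peaks but above the 28.7% of width-matched sets.

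In each fixed gene group but blood cell genes, where 3 of 6 kept one, Isha peaks were lost from more genes than they stayed at. Losses of the other proteins were of at most 2 genes per group: CP190 was lost from 2 of 9 heat shock, 2 of 13 ecdysone and 1 of 23 insulator and architectural protein genes, Su(Hw) from 1 of 5 germline and 1 of 9 ribosomal protein genes, and Mod(mdg4) from 1 of 2 insulator and architectural protein genes. Of the 80 ribosomal protein genes with mock Isha 18 still had a peak, among them RpL36, RpL22 and RpL35, and of the 25 insulator and architectural protein genes 8 did, among them Cp190 and Isha. The knockdown Isha list passed for no group, with 18 ribosomal protein genes against 12.6 in random sets (permutation test, adjusted p = 0.4305) and 8 insulator and architectural protein genes against 4.31 (permutation test, adjusted p = 0.399). CP190 lay at all 82 of its mock ribosomal protein genes and at 3 more after knockdown. Su(Hw) kept all 20 of its neuronal genes (against 12.9 in random sets, permutation test, adjusted p = 0.0192). Within 500 bp of gene ends the knockdown count was 9 of 24 against 5.75, which did not pass (permutation test, adjusted p = 0.6826).

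The su(Hw) gene (3R, 14304455 to 14308589), whose mRNA the series title links to Isha, carried peaks of all 4 proteins in mock cells near its end at 14308589, in the stretch toward Polr2I. The mock Isha peak spanned 14308003 to 14309939 and had no knockdown counterpart. It also reached into Polr2I (14309089 to 14310178), so it is not assigned to su(Hw) alone. Of all protein-coding genes, 49.7% had a mock Isha peak within 1000 bp. The Su(Hw) peak was at 14307326 to 14309275 in mock cells and at 14307328 to 14309085 after knockdown, the CP190 peak at 14307277 to 14309407 and at 14307268 to 14309417, and the Mod(mdg4) peak at 14307601 to 14308755 and at 14307593 to 14308821.

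**Figure D5:**
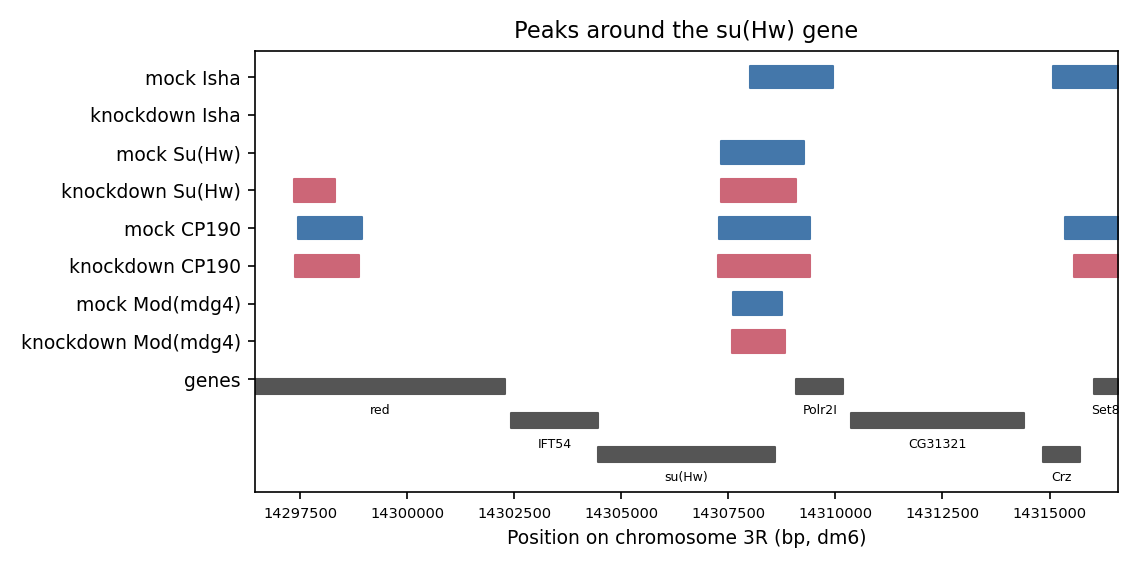
Deposited peaks of the 4 proteins in mock cells (blue) and after Isha knockdown (red), 1 list per row, along chromosome 3R (x axis, bp in dm6) within 8000 bp of the su(Hw) gene, with protein-coding genes in grey. The Isha peak at 14308003 to 14309939 is present only in the mock list, while the Su(Hw), CP190 and Mod(mdg4) peaks at the same place are present in both.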

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

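The tests on peaks found only after knockdown, on Su(Hw) peaks by the fate of their Isha peak, on matching for CP190 and Mod(mdg4), and on narrowing in every list were chosen after the result was seen. The other tests were planned.

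The kept share moved with mock Isha in opposite directions for Su(Hw), by -16.6 points, and CP190, by 5.73 points. For Mod(mdg4) the value was 9.27 points, but its interval (-0.69 to 16.4) includes 0, its percentile of 95.3 lies inside the central 95% of width-matched sets, and near gene ends it was 1.71 points (-14.9 to 11.6), so no direction is read from it. The difference between the proteins was not tested, since each has 1 list per treatment. Width accounts for part of the Su(Hw) gap, as Su(Hw) peaks with Isha had a median width of 1159 bp against 1532 bp without. Matching on width left a gap, with a kept share -6.88 points from the mean of width-matched sets. With CP190 and Mod(mdg4) matched too it was -7.72 points, below all 10000 sets in both cases. Matching used 10 bins of width, and lost Su(Hw) peaks were narrow, with a median of 787 bp against a lower quartile of 1057 bp for the mock list. Differences of width within a bin may remain, so width is not excluded as the source of the rest.

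Peaks near the calling threshold may account for what remains. Su(Hw) peaks found only after knockdown lay at mock Isha sites in 21.6% of cases against 5.10% for shared peaks, so Isha sites were over-represented among gained as well as lost Su(Hw) peaks, which is consistent with weak peaks that come and go between lists. A biological explanation, loss of Su(Hw) where Isha was lost, cannot be told apart from it. Su(Hw) peaks whose Isha peak was lost were kept -6.87 points relative to those whose Isha peak stayed (interval -16.4 to 4.63), which includes 0 and also overlaps the interval of the gap itself (-21.8 to -12.1), and an Isha peak that stayed may still have lost signal.

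The number of peaks rose for CP190 and fell for the others, with ratios of 1.08 for CP190, 0.961 for Su(Hw) and 0.836 for Mod(mdg4); the difference was not tested. Splitting of broad CP190 peaks gave a net 230 of the 687 extra peaks (33.5%), so it is not the whole cause. The narrowing was shared by all 4 lists, the highest median width ratio being 0.889. A difference of the knockdown libraries or of the peak calling that touched every antibody may account for it. The labels name 1 kind of input for Isha and another without an antibody, which Su(Hw), CP190 and Mod(mdg4) appear to share. The 4 lists are therefore not separate observations of the narrowing. Depth and fragment length stay open as explanations, as does an effect of the knockdown itself, because the lists hold no reads.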

How the results depend on the processing

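No paired analysis was possible because each list joins both replicates; leaving out a replicate, a replicate block and a stricter peak threshold could not be run either. Of 80 alternative values, 50 were counted as keeping direction and size or side of the threshold, 27 moved and 3 reversed. The cause was not tested. The 50 include the number of gene group calls above random sets, which fell from 6 to 4 at gene ends. The values with and without CP190 were added after the data were seen. Sharing of Isha with CP190 stayed past the test and that with Su(Hw) below placement under all 5 alternatives, but the shares fell, to 27.7% and 18.4% with CP190 and 1.75% and 1.41% with Su(Hw), with reciprocal overlap and with midpoints.

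With 50% reciprocal overlap the fold of Isha with Mod(mdg4) over placement turned to 1.56, kept shares were 14.1% for Isha, 88% for Su(Hw) and 90.1% for CP190, the share of Isha peaks with all 3 proteins was 0.338%, and the difference with against without Isha was -7.36 points for Su(Hw) and 7.51 for CP190. With midpoints within 250 bp these were 1.22 (reversed), 9.48%, 81.7%, 85.1%, 0.380% and, for Su(Hw), -5.63 points, whose interval (-17.1 to 3.05) included 0, unlike those of the other alternatives for Su(Hw). Merging peaks within 500 bp gave a kept share of 20.7% for Isha.

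The Su(Hw) difference was -3.90 points in the middle 50% of widths, -23.4 near gene ends and -5.67 away from them; that of CP190 was 1.22, 2.62 and 4.71. The CP190 ratio reversed to 0.868 by base pairs covered. Shares within 250 and 1000 bp of a gene end were 32.2% and 73.0% for Isha, 11.4% and 27.3% for Su(Hw), 39.7% and 57.6% for CP190, and 16.7% and 35.8% for Mod(mdg4). With peaks counted near gene ends, 3 combinations of list and gene group in place of 1 were below random sets (Hox and segmentation genes in mock Isha and knockdown CP190, neuronal genes in mock Isha), and 4 in place of 6 were above. Unknown depth limits every comparison of lists.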

Other observations

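The counts near non-coding genes and the test of Su(Hw) at CP190 peaks with Isha were chosen after the data were seen; the test against placements matched to gene ends was planned. Neighbouring non-coding genes can share 1 peak, so they are not treated as independent.

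Classes of non-coding genes differed in which proteins lay nearby. Their shares were set beside random placements of the genes, which do not compare a class with other genes. Of the 13922 protein-coding genes, 49.7% had a mock Isha peak and 8488 a mock CP190 peak, in a wider window of 1000 bp. A share above placement is therefore not read as a trait of the class, and a difference from genes in general was not tested. Of 269 snoRNA genes, whose products guide the modification of ribosomal RNA, 49.8% had a mock Isha peak within 500 bp (43.9 to 55.7%), against a mean of 10.2% in random placements of the genes, and 5.20% had one after knockdown. CP190 was near 41.3% of them and Su(Hw) near 7.43%. Of 503 antisense RNA genes 42.9% had Isha, against 13%. The genes of transfer RNA and of spliceosomal and related snRNA, by contrast, had CP190 above placement and Isha within its range. Of 290 tRNA genes 41.7% had a mock CP190 peak (36.2 to 47.5%, placements 15.8%) and 6.21% an Isha peak (placements 5.86 to 14.1%). Of 32 snRNA genes 59.4% had CP190, 50% had Su(Hw) (33.6 to 66.4%, placements 9.81%) and 6.25% had Isha (placements 0 to 21.9%). Su(Hw) was near 12.8% of tRNA genes, within the range of placements (4.83 to 13.1%). Of 1959 lncRNA genes 8.88% had Isha, below the lowest placement (10.1%), and 16.9% had Su(Hw), above the highest (15.6%). Of 260 miRNA genes 17.3% had Isha, above the highest placement (16.2%). The margins for lncRNA and miRNA genes are small, and no difference is read from them. The CP190 shares of tRNA and snRNA genes were 46.6% and 59.4% after knockdown. No peak of any list lay near the 98 annotated ribosomal RNA genes on the main arms. The Wilson upper bound of 3.77% per list covers counting error only. Whether reads could be placed uniquely at these genes is unknown, so absence of the proteins is not read from it.

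CP190 peaks with neither Isha nor Su(Hw) were the ones lost most often. They were kept in 88.5% of 1468 cases (86.8 to 90.02%), against 92.9% with Su(Hw) alone, 97.0% with Isha alone and 99.7% of 324 with both. The means of width-matched sets were 92.0% for the first class, 93.5% with Su(Hw) alone, 94.6% with Isha alone and 98.1% with both. Peaks with Su(Hw) alone thus lay slightly below peaks of like width. The class with both was the widest, with a median of 2096 bp, and most of its high share was also found in its width-matched sets.

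Isha peaks lay at CP190 sites and seldom at Su(Hw) sites, and 2 technical explanations were weighed. A shared preference for gene ends in general is not enough. The share with CP190 was 1.68 times the highest of the placements that kept the distance to gene ends. Those placements used either end of any protein-coding gene on the arm. A shared preference for promoters, or for the same subset of genes, was therefore not tested and stays open. Regions that collect signal in any immunoprecipitation would appear for Su(Hw) as well, if they passed the unknown threshold of its list. CP190 peaks with Isha carried Su(Hw) in 10.1% of cases, against 70.6% of CP190 peaks without Isha and 45.8% in width-matched sets. These counts are part of the pattern itself and were chosen after it was seen, so they cannot decide on that source. Regions that collect signal in any immunoprecipitation remain possible. Among the 10 widest Isha peaks with all 3 proteins, those in Snap25, Myo81F, cbt, ush, Ptp61F and RpLP0 appear in all 8 lists. No biological explanation was tested.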
